A study of Rattus norvegicus with 8 samples.

How the data were processed

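Libraries were made from total RNA of the right hippocampus of 8 rats, 4 per group, with the Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, STAR, HTSeq and edgeR, without versions for the last 3 and without the role of each. The aligner settings, genome build, annotation release and strand setting are not given in the sources used here. Overlapping genes and close paralogs may therefore share or lose reads in ways that the counts do not show.

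The deposited count table holds whole-number read counts for 26405 Ensembl gene IDs, with 1 column per rat. It also holds 3 summary rows in the form that HTSeq writes, per the file headers. These rows were left out of library sizes and tests. The one for reads assigned to no annotated feature, called reads outside genes below, held 30.7% to 32.9% of the tabulated reads per library. The other 2 held 0. The feature type counted is not given, so the reads outside genes may include reads in introns of annotated genes. The second deposited table holds a normalised signal for 13595 IDs. It is labelled as log2 CPM, but its deposited signal values are linear and reach between 32630 and 46718 per library. Within each library, the deposited count divided by the signal was the same number for every ID, with a largest relative deviation of 3.05e-09. That number equals the library size over the kept IDs times edgeR's TMM (trimmed mean of M values) factor. The IDs kept are those with over 1 CPM in at least 4 libraries. This table was used only for an alternative, on a log2(value + 1) scale, which understates the change of low genes.

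Groups and replicate numbers came from the sample titles, and table columns were matched to samples through the rat identifiers in the sample descriptions. The 28 pairs of libraries differed by 5.74 to 54.1 chi-square units per degree of freedom over IDs with at least 20 reads, so no library was a second deposit of another. Counts were analysed in R 4.3.3. IDs were kept by edgeR 4.0.16 filterByExpr with its defaults (minimum count 10, minimum total 15), which left 14522, and libraries were scaled by TMM. The comparison of the IGF1 with the DsRed group used glmQLFit and glmQLFTest with group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 11.8%, with 6 residual degrees of freedom and 3.77 prior degrees of freedom. Standard errors of log2 fold changes were taken as the fold change over the square root of the F statistic. CPM values are counts divided by the TMM-scaled library size, on edgeR's CPM scale. Log2 CPM for principal components, Spearman correlations and separation used a prior count of 2. Single library measures were compared by exact two-sided permutation of the 8 libraries, 8 measures in all, adjusted together.

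The procedure was tested on simulated data drawn from the means and library sizes of these libraries, with 200 IDs changed between the IGF1 and DsRed libraries. The low count filter left 14397 simulated IDs, 195 of them changed. The quasi-likelihood test recovered 14.0% of the tested IDs changed 1.25-fold, 56.3% at 1.5-fold, 79.6% at 2-fold and 97.9% at 3-fold. It called 120 changed and 5 unchanged IDs, and the likelihood ratio test called 128 changed and 26 unchanged IDs. Of the unchanged IDs, 4.81% had an unadjusted p under 0.05. Simulated counts were drawn independently for each ID and library from the fitted dispersions, so no library stood apart and IDs did not vary together. The fitted dispersions were also taken as the true ones, and recovery after adjustment depends on how many IDs are changed, here 200. Recovery in the real data, where IGF1 replicate 1 stood apart, may therefore be lower.

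The test, its covariates, the rule for genes named singly and the alternatives, apart from those given below as chosen later, were fixed before the data were examined. That rule called for the transcript of Igf1 first. It then took the genes past the threshold with a symbol, a mean log2 CPM of at least 1 and non-overlapping groups. A direction with too few of these was filled by smallest unadjusted p under the same conditions, and members of fixed gene lists followed. Neither the deposited tables nor the rat gene table used here pairs Ensembl IDs with symbols, and 0 of the IDs matched. The files therefore do not pair IDs with names, and the rule was applied without the symbol condition and limited to 2 IDs per direction. The Igf1 transcript, the gene and cell type lists and the covariates built from them were not analysed here. The counts at an unadjusted p under 0.05, the separated IDs and the share of the 10 most abundant IDs were added after the counts had been seen.

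Alternatives were DESeq2 1.42.0, edgeR's likelihood ratio and exact tests, limma 3.58.1 voom and limma trend on the deposited signal. Other scalings, low count filters and thresholds were tried, as were a robust fit, the replicate number as a block, 1 surrogate variable (sva 3.50.0) and leaving out each library in turn. DESeq2 left the adjusted p undefined for 9703 IDs, which were not counted as calls. The alternatives chosen later were the authors' filter, leaving out the 10 most abundant IDs, library quality weights, a pseudocount of 0.1, leaving out both libraries numbered 1, and all those for the results added after the counts had been seen.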

Results

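The hippocampal transcriptome was measured by RNA sequencing in 8 female Sprague-Dawley rats aged 28 months. The rats had received an adenoviral vector into the cerebral ventricles. In 4 rats, the IGF1 group, the vector carried the rat gene for insulin-like growth factor I, a peptide hormone with trophic actions on neurons and glia. The other 4 rats, the DsRed group, received the placebo vector, named in the labels for DsRed, a red fluorescent protein. Each library was made from the right hippocampus of 1 rat, so the spread between libraries within a group includes the spread between animals. The question was which hippocampal transcripts differ between aged rats given the IGF-I vector and aged rats given the placebo vector.

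Reads assigned to genes numbered 27377086, 19031525, 21696848 and 17504428 in IGF1 replicates 1 to 4, and 16347636, 25648675, 22893172 and 18005777 in DsRed replicates 1 to 4. The group means differed by less than the spread between libraries, with an exact two-sided permutation p of 0.83. A further 30.7% to 32.9% of the reads tabulated in each library were assigned to no annotated feature, which may include reads in introns. At this depth between 17791 and 18620 gene IDs had at least 1 count per library, and 14522 of the 26405 IDs in the count table were abundant enough to be tested.

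The libraries did not separate by group. The first principal component of log2 CPM, the read count scaled to library size, held 31.6% of the variance and set IGF1 replicate 1, with a score of 42.0, apart from the other 7 libraries, which lay between -16.0 and 2.89. The second held 20.9% and set DsRed replicate 1, with a score of 31.5, apart from the rest. The difference between the groups along the first 3 components did not pass exact two-sided permutation tests, with p of 0.286, 0.657 and 0.571. Here 4 libraries against 4 allow a smallest p of 0.0286. Spearman correlations across genes were high for every pair of libraries, between 0.984 and 0.997. IGF1 replicate 1 had a mean correlation of 0.986 with the other libraries, against 0.991 to 0.994 for those libraries.

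**Figure D1:**
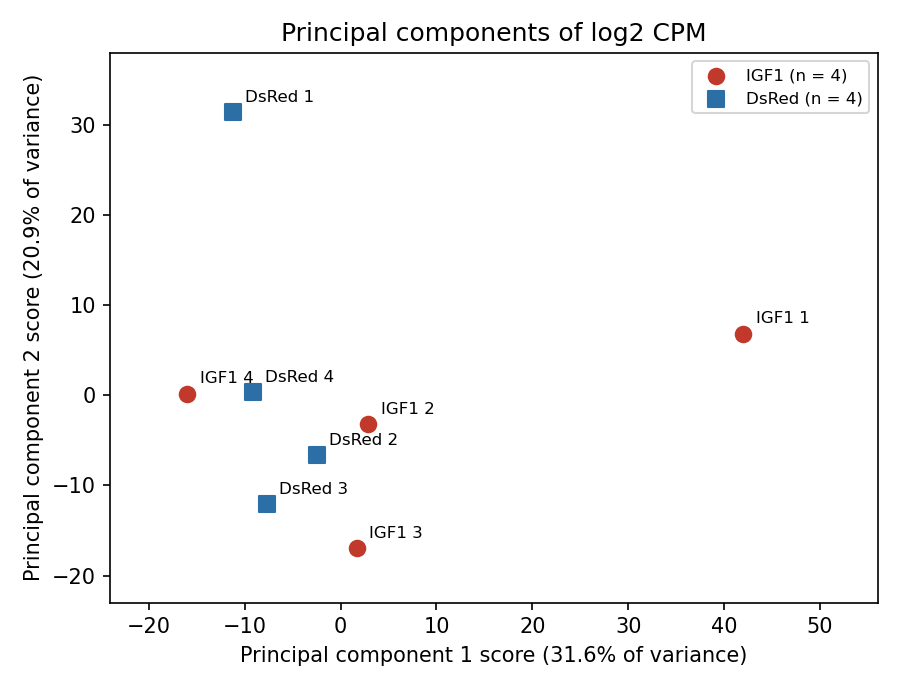
Scores of the 8 libraries on principal components 1 and 2 of log2 CPM, which hold 31.6% and 20.9% of the variance, with 1 point per library and 4 libraries per group. IGF1 replicate 1 lies at 42.0 on component 1 and DsRed replicate 1 at 31.5 on component 2, and the other 6 libraries of both groups overlap.

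Hippocampal transcript levels in rats given the IGF-I vector lay close to those in rats given the placebo vector. The median absolute log2 fold change over the 14522 IDs was 0.08. A fitted difference of more than 1.5-fold was found for 294 IDs (2.02%) and of more than 2-fold for 67, of which 38 were higher and 29 lower in the IGF1 group. Among IDs with a mean log2 CPM of at least 1, 31 differed by more than 2-fold, 20 of them higher and 11 lower. None of these differences passed the test across genes, as given next.

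No gene ID passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.234. At an unadjusted p under 0.05 the same test listed 958 IDs, 515 higher and 443 lower in the IGF1 group, where 726 are expected by chance. In 684 IDs (398 higher and 286 lower) every library of one group lay above every library of the other. That is 4.71% of the IDs tested, where chance gives 2.86%, or 415 IDs. RLE and upper quartile scaling gave nearly the same split of the unadjusted list, 515 higher and 443 lower, and 516 higher and 453 lower. With libraries scaled by total counts only, 250 IDs at an unadjusted p under 0.05 were higher and 784 lower, and 191 separated IDs were higher and 567 lower. That scaling moved the median log2 fold change of all IDs from 0.0027 to -0.026. The unadjusted count was 626 without DsRed replicate 2 and 1439 without IGF1 replicate 4. At an adjusted p under 0.05, leaving out DsRed replicate 2 gave 1 call, and leaving out any other single library gave 0.

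Other tests on the same counts made a small number of calls, most of them lower in the IGF1 group. edgeR's likelihood ratio test called 11 IDs, 10 lower and 1 higher, and its exact test called the same 11. DESeq2 called 13, of which 10 were lower and 3 higher, and limma voom called 0. The likelihood ratio, exact and DESeq2 tests shared 10 calls, 9 of them lower, and 14 IDs were called by at least 1 of the 3. The 10 lower IDs of the likelihood ratio test had log2 fold changes between -3.41 and -0.41. The large end of this range came from IDs with few reads. ENSRNOG00000020951, at -3.41, had 0.13 ± 0.08 CPM in the IGF1 group and 1.52 ± 1.51 CPM in the DsRed group (SD, n = 4 each). ENSRNOG00000009907, at -2.53, had a mean log2 CPM of -1.12 and was not called by DESeq2. All 11 calls of the likelihood ratio test had non-overlapping groups, and their adjusted p in edgeR's quasi-likelihood test lay between 0.234 and 0.743. At an unadjusted p under 0.05 the likelihood ratio test listed 738 IDs, the exact test 711 and limma voom 995. Each tested 14522 IDs, where 726 are expected by chance. DESeq2 listed 859 of the larger set of 20653 IDs to which it gave a p, fewer than chance gives.

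**Figure D2:**
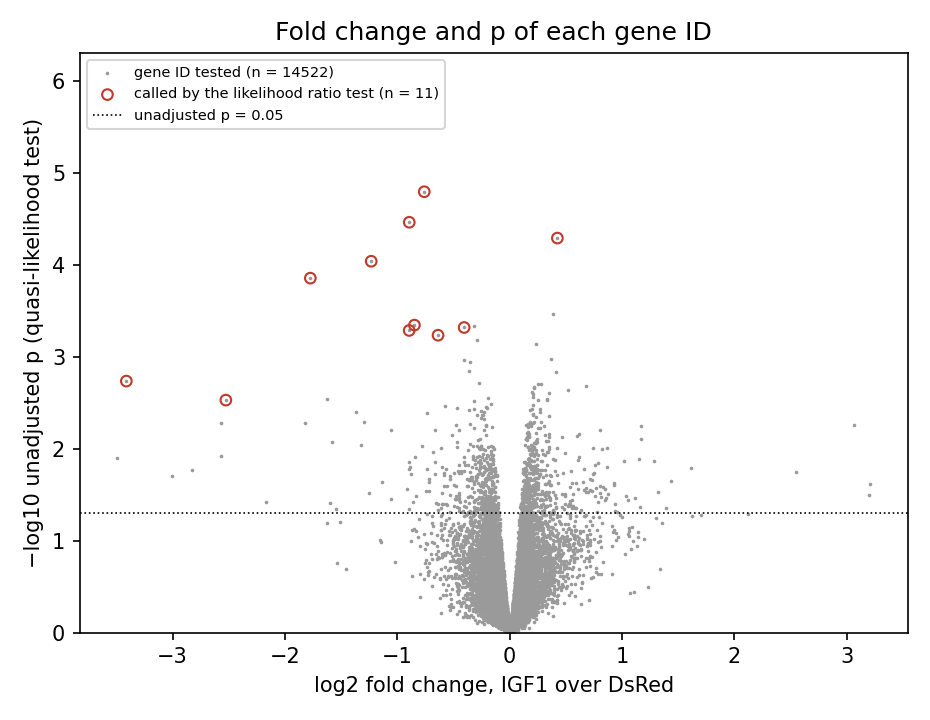
Log2 fold change of the IGF1 group over the DsRed group against -log10 of the unadjusted p of edgeR's quasi-likelihood test, with 1 grey point for each of the 14522 gene IDs and a dotted line at an unadjusted p of 0.05. Red circles mark the 11 IDs called by edgeR's likelihood ratio test, 10 of them lower in the IGF1 group; the quasi-likelihood test called 0 after adjustment.

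The 4 IDs described singly had the smallest unadjusted p in each direction among IDs with non-overlapping groups. The files do not pair the Ensembl IDs with gene symbols, so they are given as deposited, and no chromosome position is given. None of the 4 passed the adjusted threshold of the quasi-likelihood test. ENSRNOG00000003300 had a mean of 18.0 ± 0.91 CPM in the IGF1 group and 30.5 ± 4.09 CPM in the DsRed group (SD, n = 4 each), a log2 fold change of -0.76 with a standard error of 0.097. It was lower in all 4 IGF1 libraries, which lay between 17.3 and 19.4 CPM, against 24.9 to 34.7 CPM in the DsRed libraries. Its adjusted p was 0.234 in edgeR's quasi-likelihood test, 2.61e-07 in edgeR's likelihood ratio test and 4.93e-07 in DESeq2, and 0.0169 in the quasi-likelihood test without DsRed replicate 2. Over the 26 alternative settings, edgeR, DESeq2 and limma gave it an adjusted p between 2.50e-07 and 0.866. ENSRNOG00000014205 had 8.92 ± 1.03 CPM in the IGF1 group and 16.6 ± 2.59 CPM in the DsRed group (SD, n = 4 each), a log2 fold change of -0.89 with a standard error of 0.125. Its adjusted p was 0.249 in edgeR's quasi-likelihood test, 2.12e-06 in edgeR's likelihood ratio test and 4.95e-06 in DESeq2, and lay between 2.12e-06 and 0.866 over the same alternatives.

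In the other direction, ENSRNOG00000029145 had 20.7 ± 1.10 CPM in the IGF1 group and 15.4 ± 0.51 CPM in the DsRed group (SD, n = 4 each). Its log2 fold change was 0.42 with a standard error of 0.062. The adjusted p was 0.249 in edgeR's quasi-likelihood test, 0.00227 in edgeR's likelihood ratio test and 0.00632 in DESeq2, and lay between 0.00218 and 0.913 over the 26 alternatives. ENSRNOG00000026690 had 12.6 ± 0.45 CPM in the IGF1 group and 9.66 ± 0.52 CPM in the DsRed group (SD, n = 4 each), a log2 fold change of 0.39 with a standard error of 0.072. Its adjusted p was 0.743 in edgeR's quasi-likelihood test, 0.0788 in edgeR's likelihood ratio test and 0.129 in DESeq2, and lay between 0.0788 and 0.913 over the 26 alternatives. These 4 IDs were each supported by between 136 and 805 reads per library. In an exact permutation test each gave a p of 0.0286, the smallest that 4 libraries against 4 allow, as their selection for separated groups requires.

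**Figure D3:**
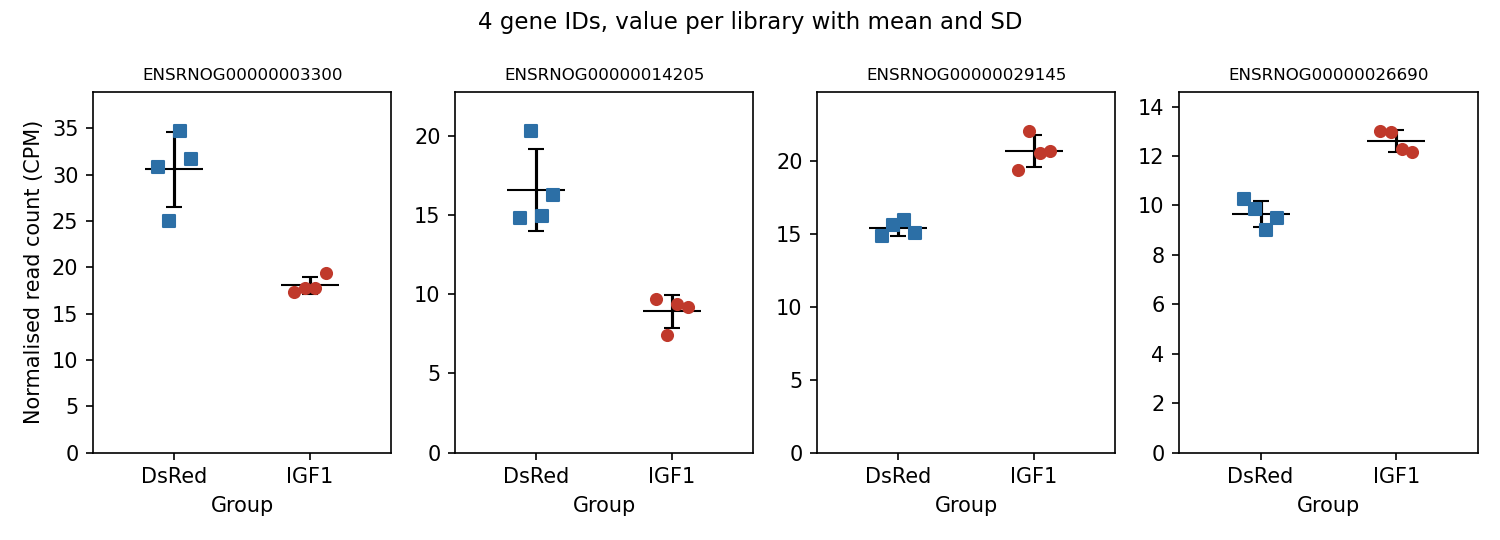
Normalised read count in CPM of 4 gene IDs in each library of the DsRed group (squares, n = 4) and the IGF1 group (circles, n = 4), with the mean as a bar and the SD as an error bar, on axes that start at 0. ENSRNOG00000003300 and ENSRNOG00000014205 were lower in every IGF1 library than in every DsRed library, ENSRNOG00000029145 and ENSRNOG00000026690 were higher, and none passed an adjusted p of 0.05 in edgeR's quasi-likelihood test.

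The share of counts on the most abundant transcripts was larger in the IGF1 group, and whether the difference passed its test depended on the choice of IDs and libraries. The 10 most abundant IDs took 15.1% ± 1.38 of the gene counts in the IGF1 group and 12.6% ± 0.89 in the DsRed group (SD, n = 4 each). The difference of 2.51 percentage points had an exact two-sided permutation p of 0.0571, and 0.457 after Benjamini-Hochberg adjustment over the 8 library measures compared. The unadjusted exact permutation p was 0.0286, the smallest possible, for the 20 most abundant IDs (2.72 points) and without IGF1 replicate 3 (3.01 points), and lay between 0.0286 and 0.114 over the 12 alternatives that allow a p under 0.05. In the IGF1 group 3 of the 4 libraries lay above the highest DsRed library, at 13.9%, and the lowest IGF1 library was at 13.6%. Of the 10 IDs, 9 had higher fitted levels in the IGF1 group, with log2 fold changes of 0.28 to 0.35. In edgeR's quasi-likelihood test their unadjusted p lay between 0.00829 and 0.0425 and their adjusted p was 0.743 each. The 9 are not separate observations, since they varied together across the 8 libraries. Over their 36 pairs Pearson's r was at least 0.937 and Spearman's rho at least 0.929, with exact permutation p of at most 0.000546 and 0.00223, or 0.000682 and 0.00279 after Benjamini-Hochberg adjustment over 45 pairs. Without the 2 libraries farthest from the median of the more abundant ID of each pair, r was at least 0.878. The remaining ID had a log2 fold change of -0.11 with an adjusted p of 0.876 in the same edgeR test. Across the 8 libraries it varied against each of the 9. Spearman's rho was -0.905 to -0.833 and Pearson's r -0.794 to -0.665. Their exact permutation p, adjusted over the same 45 pairs, was at most 0.0154 and 0.0722. Without the 2 libraries farthest from the median of the more abundant ID of each pair, r was -0.884 to -0.308. For some of the 9 the opposition was therefore weaker without these libraries.

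**Figure D4:**
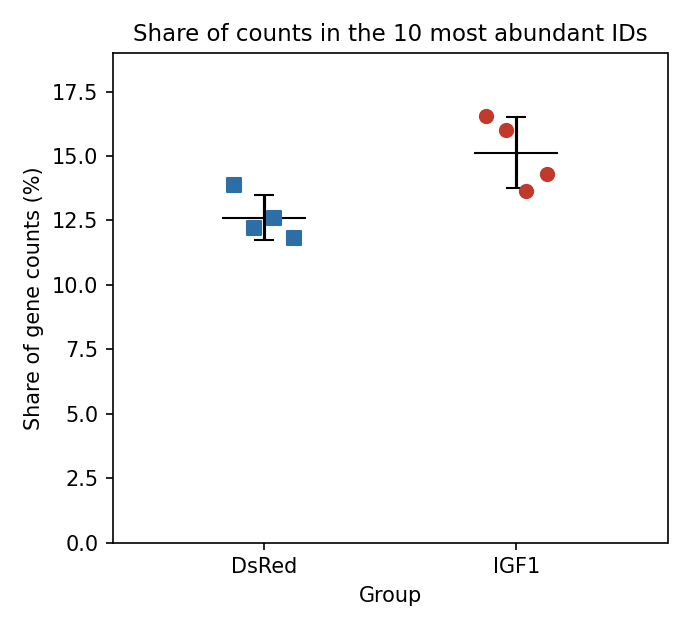
Share of the gene counts, in percent, taken by the 10 most abundant gene IDs in each library of the DsRed group (squares, n = 4) and the IGF1 group (circles, n = 4), with the mean as a bar and the SD as an error bar. The means were 12.6% and 15.1%, and the lowest IGF1 library, at 13.6%, lay below the highest DsRed library, at 13.9%.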

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

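The tests of reads outside genes and of a label swap for IGF1 replicate 1, the test without that library for the share of abundant transcripts, and the exact tests of that share with a covariate, were chosen only after the result was seen. Library measures and the 4 IDs described singly were searched for values far from the rest of their group, 28 sets of 4 libraries in all. The 5 values given here had a gap to the nearest library that took up 0.843 to 0.930 of the group's range. Chance gives about 1 in 20 such sets, and several of the measures come from the same log2 CPM values, so the 5 are not independent.

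IGF1 replicate 1 accounts for 3 of them. Its mean Spearman correlation with the other libraries was 0.986, against 0.9927 to 0.9933 for the other IGF1 libraries. It had 136 IDs more than 2-fold above the median of the 8 libraries, against 1 to 22 in the rest of its group, and 114 more than 2-fold below it, against 6 to 23. Sequencing depth is argued against: with all libraries thinned to the smallest total, its mean correlation still lay 8.68 SD below the mean of the other 7. It had the most gene counts of the 8 libraries, so thinning tested only whether its greater depth set it apart. A label swapped between the groups is argued against as the cause of its distance, since its mean correlation with the DsRed libraries was 0.985, against 0.992 to 0.997 between those libraries. With the other IGF1 libraries it was about as low, at 0.986, so these values do not settle which label is right. Reads assigned to no annotated feature stay open: its share of 32.9% was the highest of the 8, but its gap was only 0.399 of the group's range. No biological explanation specific to this rat was tested, and a different mix of tissue in the dissection was not tested without gene names.

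The other 2 values concern DsRed libraries. DsRed replicate 1 had 62 IDs more than 2-fold below the median of the 8 libraries, against 5 to 11 in the rest of its group. DsRed replicate 4 had a score of 23.6 on the third principal component, which held 14.8% of the variance, against -4.54 to -0.64 in the rest of its group.

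The larger share of counts on the 10 most abundant IDs in the IGF1 group, 2.51 percentage points, had an exact permutation p of 0.0571 and passed 0.05 under 2 of the 12 alternatives that allow it, so chance alone may account for it. The difference was 2.49 points with the total count as a covariate, 1.87 points with the share of reads outside genes as a covariate, and 2.04 points without IGF1 replicate 1. Exact permutation of the group labels in these 3 fits gave p of 0.0571, 0.114 and 0.0857. The first 2 differences lay beyond the bound of 2 standard errors set beforehand. With 5 residual degrees of freedom that bound is narrower than a 95% interval. The 95% interval was 0.193 to 4.79 points with the total count and -0.52 to 4.26 with the reads outside genes. Without IGF1 replicate 1 it was 0.011 to 4.06 points. None of the 3 exact tests passed, but the exact p without a covariate was already 0.0571. The total count left the difference nearly unchanged, which argues against depth as the source of the whole difference. Reads outside genes, that library, an effect of the vector and chance stay open.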

How the results depend on the processing

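The variants with the authors' filter, without the 10 most abundant IDs, with library quality weights, with a pseudocount of 0.1 and without both libraries numbered 1 were chosen only after the result was seen, as were all variants of the unadjusted, separated and abundant-share results. A 1.5-fold minimum could not add any calls. Of 27 alternatives that could give more than 0 calls, 1 at an adjusted p under 0.10 and the rest under 0.05, 23 gave 0. The exceptions were DESeq2 with 13 (3 higher and 10 lower in the IGF1 group), edgeR's likelihood ratio test and its exact test with 11 each (1 higher and 10 lower), and the fit without DsRed replicate 2. Leaving out 1 library gave 0 to 1 IDs past the threshold, 0 higher and 0 to 1 lower. The cause of these differences was not tested. Leaving out 1 library gave 626 to 1439 IDs at an unadjusted p under 0.05 and 980 to 1435 separated IDs, and leaving out both libraries numbered 1 gave 1891 separated IDs. Fewer libraries raise the separated count by construction: chance gives 5.71% with 3 against 4 libraries and 10% with 3 against 3, where 6.73% to 9.72% and 13.01% were found. Each of the 4 IDs described singly kept its direction in all 26 alternatives. The 4 were picked for non-overlapping groups in these same libraries. Their direction could therefore hardly reverse, and its stability is no separate evidence for a difference. Log2 fold changes were -0.85 to -0.69 for ENSRNOG00000003300 and -0.99 to -0.78 for ENSRNOG00000014205. They were 0.39 to 0.46 for ENSRNOG00000029145 and 0.35 to 0.41 for ENSRNOG00000026690. The difference in share was positive in all 14 alternatives, at 1.802 to 3.01 percentage points. Its exact permutation p fell to 0.0286 with the 20 most abundant IDs (2.72 points), and leaving out 1 library gave 2.04 to 3.01 points with p of 0.0286 to 0.114. With the replicate number as a replicate block the quasi-likelihood test called 0 IDs and listed 878 at an unadjusted p under 0.05, so it changed no call. The share was higher in the IGF1 library of all 4 same-numbered pairs, with an exact sign-flip permutation p of 0.125, the smallest that 4 pairs allow. The deviations of same-numbered libraries correlated at 0.055, 0.126, 0.244 and 0.134. Every IGF1 library, but not every DsRed library, correlated best with its own number. The plan set no block, since the labels name separate rats, and the numbers were not taken to pair them. These correlations, all positive, do not exclude a batch shared by same-numbered libraries. The covariates built from marker genes and all alternatives for Igf1 and the gene lists were not run. Depth limits the low end: low-count IDs were filtered out, and with none filtered 20678 IDs gave 0 calls.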

Other observations

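The splits were chosen before their results were seen, for counts that were already known. Each count from the comparison of the groups was set against all 35 ways to split the 8 libraries into 4 and 4, the real one included. The real split gave 0 IDs at an adjusted p under 0.05 in edgeR's quasi-likelihood test and the highest of the others gave 2; all 35 reach 0 by construction, so this count tests nothing. The 958 IDs at an unadjusted p under 0.05 were matched or exceeded by 4 of the 35 splits, with 1343 in the highest of the others. The 684 separated IDs were matched or exceeded by 3 of the 35, with 856 in the highest of the others. The 11 calls of the likelihood ratio test were matched or exceeded by 8 of the 35. Chance can therefore not be excluded for the unadjusted, separated and likelihood ratio counts.

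The highest of the other splits gave 60 calls in the likelihood ratio test, several times the 11 of the real one. It set IGF1 replicates 1, 2 and 3 with DsRed replicate 2 against the rest. The same split gave 0 calls in the quasi-likelihood test, 900 IDs at an unadjusted p under 0.05 and 494 separated IDs, each no higher than in the real split. Whether its many calls come from a structure among the libraries or from excess calls of the likelihood ratio test, which also called 26 unchanged IDs in the simulated data, was not tested.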
